A study of Lactuca sativa with 20 samples.

How the data were processed

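Whole lettuce seedlings (*Lactuca sativa*, Little Gem) were profiled by RNA sequencing after 2 h in solution. The 20 libraries fall into 7 groups by the treatment that the labels give. Water, ABA, ACC, CLE12p, CLE12p with ABA, and CLE12p with ACC had 3 libraries each, and 0.02% ethanol had 2. ABA, ACC and CLE12p were each given at 10 µM. The study's design text lists the last combination as ABA with ACC, whereas the labels of its 3 libraries name CLE12p with ACC, and the labels were followed. The labels do not say whether the replicates were separate batches of seedlings, so the spread between libraries may be partly technical. The p-values measure that spread pooled over the 7 groups, which differed in their own spread.

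The deposited values are raw read counts per gene model, as whole numbers with 1 column per library and no pooling. Per the labels' protocols, total RNA was treated with DNase and made into libraries by standard Illumina methods. STAR 2.7.10a is named in the submitters' processing notes. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical copies therefore cannot be told apart, and the level of any single gene model carries that uncertainty. Library totals ran from 18614220 to 27101622 counts. The table held 37828 gene models, of which 9654 had 0 counts in every library. There were 0 rows without a gene identifier and 0 columns of counts that were left unused. The 19 pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom from 3.59 to 24.9), so no library was counted as a repeat of another.

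Gene identifiers of the table were looked up in a reference gene table of assembly Lsat_Salinas_v11 with 51651 genes. Of the 37828 identifiers 0 matched, and the count table itself pairs identifiers with no names. The 36 gene lists that had been fixed before the data were examined therefore had 0 members, and neither their tests nor the alternatives planned for those tests could be run. Gene names and positions are not used here. Genes named in the text were chosen by a rule fixed beforehand for this case. In each comparison, among genes past the threshold with a mean of at least 1 log2 CPM (reads scaled to the library total) and with no overlap between the libraries of the groups compared, at most 2 genes with the highest and 2 with the lowest fold change are given by identifier. Where a comparison had 10 or fewer calls, all are given.

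Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by its filterByExpr function with a minimum of 10 counts, which left 23413 genes. Libraries were scaled with TMM factors (from 0.961 to 1.03), and a model of group means was fitted to all 20 libraries with the quasi-likelihood method, so that the 7 groups shared an estimate of the spread. The common biological coefficient of variation was 0.117. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. The 8 comparisons were ethanol against water, ABA against ethanol, ACC against water, CLE12p against water, CLE12p with ABA against ABA, CLE12p with ACC against ACC, and the interactions of CLE12p with ABA and with ACC. An interaction is the peptide's log2 fold change with the hormone minus that without it. The labels do not say which control belongs to which treatment. Ethanol was taken as the control of ABA and water as that of ACC and of the peptide, with the other control and both pooled as alternatives. Group levels are given as CPM with the SD between libraries, and log2 fold changes with standard errors. Each standard error was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F.

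Whether the peptide changed the size of a hormone response was tested over sets of genes. ABA response genes were those past the threshold for the mean of ABA and CLE12p with ABA against ethanol. ACC response genes were those past it for the mean of both ACC treatments against the mean of water and CLE12p. The difference tested was the peptide's log2 fold change in the presence of the hormone, signed so that a value above 0 is a larger response. The choice of ACC response genes holds the peptide on both sides, so a peptide effect equal with and without ACC does not enter it. The choice of ABA response genes holds the peptide only on the side of ABA. A peptide effect in ABA therefore enters that choice and its signs, and can push the signed difference above 0. The signed set was tested with the rotation test fry of limma 3.58.1 on log2 CPM with voom weights. That test asks whether the genes moved on balance in 1 direction and does not compare them with other genes. The mean signed log2 CPM of each library (prior count of 2) gave a score per library, and 3 against 3 libraries were compared with an exact two-sided permutation test, whose smallest possible p is 0.1. Correlations of fold changes were computed across 18908 genes with a mean of at least 1 log2 CPM. Genes are not independent replicates, so these correlations carry no p-value. Ratios for named genes with 3 counts or fewer over a group compared carry an exact binomial interval at 95%, and a group with 0 counts was set to a floor of 3 counts over the group. Intervals and floors cover counting error only.

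The steps were tested on simulated counts over 23368 genes in 5 simulations. Counts were drawn with the real library sizes, the mean of each gene over all libraries and 1 dispersion per gene for all groups. Each simulation had 200 changed genes for the contrasts of ABA and ACC with their controls and 400 for the other 2. Of genes changed by 1 on the log2 scale, 82.0% were found for ABA against ethanol, 90.4% for ACC against water, 89.6% for CLE12p with ABA against ABA and 75.6% for the CLE12p by ABA interaction. For a change of 2 the shares were 98.8%, 99.4%, 99.6% and 97.3%. The changed genes were drawn from those with a mean of at least 1 log2 CPM, so detection at lower levels was not measured. Real peptide groups varied more, with a median SD per gene of 0.135 to 0.149 log2 CPM against 0.0985 to 0.123 in the others. Shares for the contrasts that hold the peptide may therefore be too high. CLE12p against water was not simulated with changed genes. False calls made up 3.83%, 5.01%, 4.83% and 6.08% of all calls in the same order. Shared water controls were simulated with 20 draws of unchanged groups.

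Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, no filter on low counts, a mean of at least 50 counts, only the libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 1, the other controls, other choices of response genes, and the removal of each library in turn. Computations outside R used Python 3.11.15 with matplotlib 3.10.9 for the plots.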

Results

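Transcript levels were measured in whole lettuce seedlings held for 2 h in water, in 0.02% ethanol, or in 10 µM of ABA, ACC or CLE12p, or in CLE12p together with ABA or ACC. ABA is abscisic acid, a plant stress hormone, and ACC is the direct precursor of ethylene, the gaseous hormone of ripening and senescence. CLE12p is the peptide that the study names for its gene *LsCLE12*. CLE peptides are short secreted signals of plants. The series title places the peptide in the context of delayed senescence, and the combinations ask how it acts beside each hormone. Each group held 3 libraries, except ethanol with 2. Library totals lay between 18614220 and 27101622 counts, and 23413 genes were tested. The gene identifiers could not be matched to names, so the responses are described as sets of genes with a few identifiers each.

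Treatment set the main axes of variation. The first principal component of log2 CPM held 33.5% of the variance, and the libraries with ABA lay between 36.9 and 66.5 on it, while all others lay between -43.8 and -4.91. The second held 13.1%. On it the control libraries lay between 29.1 and 37.8, ACC between -3.99 and 2.85, CLE12p between -22.9 and 11.4, and CLE12p with ACC between -26.6 and -25.3. The ABA libraries, at 0.710 to 5.61, were separated from the libraries of CLE12p with ABA, at -42.0 to -17.1. Spread within a group was widest for CLE12p alone, with a median SD per gene of 0.149 log2 CPM over 3 libraries. CLE12p with ACC followed at 0.137 and CLE12p with ABA at 0.135. Groups without the peptide were narrower, at 0.123 for water, 0.105 for ACC, 0.101 for ABA and 0.0985 for ethanol with 2 libraries.

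**Figure D1:**
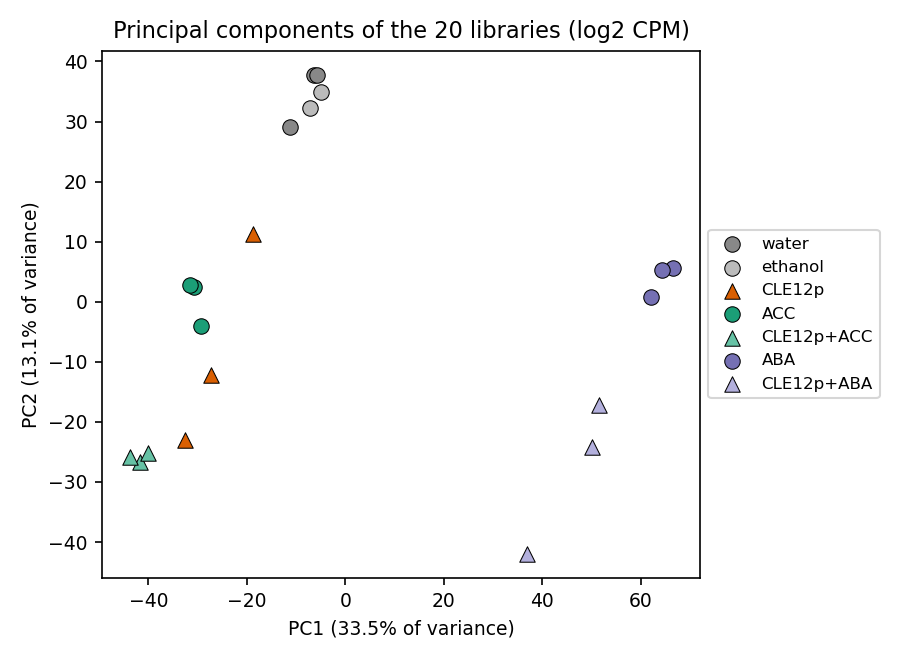
Scores of the 20 libraries on the first and second principal components of log2 CPM, 1 point per library, with triangles for treatments that hold CLE12p. The libraries with ABA lie to the right, and libraries with the peptide lie below those of the matching treatment without it, with CLE12p replicate 2 at 11.4 on the second component.

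Ethanol against water asked whether the 2 controls differed. In the edgeR test 0 of 23413 genes were called, while 1251 had an unadjusted p below 0.05. DESeq2 also called 0 genes, with 1261 at an unadjusted p below 0.05. The comparison rests on 2 ethanol libraries, and 1 gene was called without water replicate 2.

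ABA changed the most genes of any single treatment against its control. Against ethanol, 1206 genes rose and 1172 fell, with a median absolute change of 1.71-fold among the calls. Lsat_1_v5_gn_2_78000 rose from 0.139 ± 0.0768 CPM (SD, n = 2) in ethanol to 22.5 ± 2.63 CPM (SD, n = 3) in ABA, a log2 fold change of 7.31 ± 0.38 (SE; adjusted p = 2.09e-11). Lsat_1_v5_gn_9_35501 rose by 6.80 ± 0.66 on the log2 scale (adjusted p = 4.30e-07). In the 2 ethanol libraries the first gene had 2 and 4 counts and the second 1 and 3. With so few counts, the standard errors understate the uncertainty of both changes. Lsat_1_v5_gn_4_50160 had 167 counts over the 2 ethanol libraries and 0 over the 3 ABA libraries, which is 81.0-fold lower against a floor of 3 counts over the group (adjusted p = 1.79e-08). The lower 95% counting limit of its ratio was 65.2. Lsat_1_v5_gn_1_91241 had 298 counts in ethanol and 3 in ABA, a ratio of 144.6 (95% counting interval 49.0 to 705; adjusted p = 1.40e-09). Those 3 counts all lay in 1 ABA library. The peptide changed none of the genes named above past the threshold in ABA. The levels of the rising pair in CLE12p with ABA were 18.9 ± 1.26 and 8.99 ± 1.46 CPM (SD, n = 3), and those of the falling pair were 0.0148 ± 0.0257 and 0.0874 ± 0.115 CPM. The number of calls was 1537 without ethanol replicate 1, 1396 without ethanol replicate 2, and 3916 with both controls pooled.

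ACC raised 1165 genes and lowered 730 against water, and the changes were smaller than with ABA, at a median of 1.495-fold among the calls. Lsat_1_v5_gn_4_7141 rose from 0.925 ± 0.382 to 8.63 ± 2.90 CPM (SD, n = 3), by 3.22 ± 0.35 on the log2 scale (SE; adjusted p = 6.13e-06). Lsat_1_v5_gn_6_12141 rose by 3.13 ± 0.54 (adjusted p = 6.68e-04) and also rose with CLE12p alone (adjusted p = 0.00411), to 4.92 ± 0.0316 CPM. Lsat_1_v5_gn_3_93020 fell from 5.10 ± 0.957 to 0.352 ± 0.351 CPM, a log2 fold change of -3.81 ± 0.40 (adjusted p = 3.70e-06), and Lsat_1_v5_gn_8_10000 fell from 10.2 ± 2.18 to 2.57 ± 0.258 CPM (-1.98 ± 0.26; adjusted p = 5.16e-05). The latter was also lower with CLE12p (-0.94; adjusted p = 0.0285) and with ABA (-1.52; adjusted p = 6.34e-04). The number of calls fell to 1097 without water replicate 1, 1202 without ACC replicate 1 and 1224 without ACC replicate 3.

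CLE12p alone changed 1251 genes against water, and 81.5% of them rose (1019 higher, 232 lower), compared with 50.7% for ABA and 61.5% for ACC. The median change among the calls was 1.56-fold. Of the 306 calls with an absolute log2 fold change of at least 1, 289 rose. Lsat_1_v5_gn_6_96701 rose from 0.293 ± 0.154 to 12.1 ± 10.0 CPM (SD, n = 3), by 5.33 ± 1.11 on the log2 scale (SE; adjusted p = 0.00456), with single peptide libraries from 0.822 to 19.9 CPM. Lsat_1_v5_gn_8_6481 rose from 0.339 ± 0.154 to 4.77 ± 2.85 CPM (3.78 ± 0.55; adjusted p = 1.09e-04). Lsat_1_v5_gn_5_70600 fell from 12.6 ± 3.08 to 4.90 ± 1.63 CPM (-1.35 ± 0.33; adjusted p = 0.0155), and Lsat_1_v5_gn_1_77780 fell from 17.1 ± 1.72 to 6.75 ± 0.486 CPM (-1.34 ± 0.18; adjusted p = 3.81e-05). The call of Lsat_1_v5_gn_5_70600 was lost without water replicate 1 or 2 or CLE12p replicate 1 or 3, and that of Lsat_1_v5_gn_1_77780 against ethanol (-0.50; adjusted p = 0.171). The number of calls was 2073 without CLE12p replicate 2, 757 and 686 without CLE12p replicates 1 and 3, 712 and 636 without water replicates 1 and 2, 743 when only the libraries compared were fitted, and 1943 with both controls pooled.

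**Figure D2:**
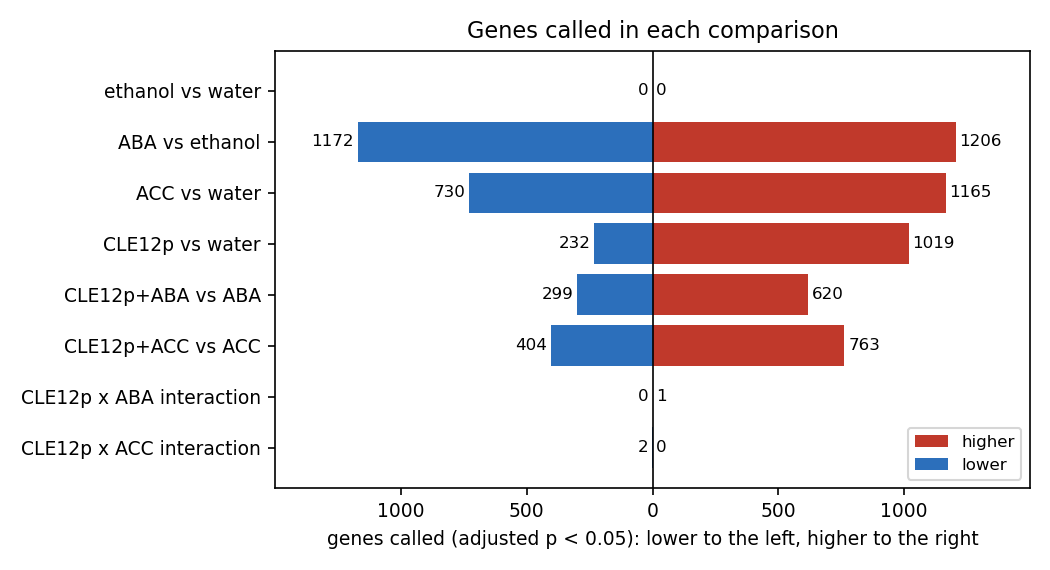
Number of genes called at an adjusted p below 0.05 in each of the 8 comparisons (edgeR), with higher genes to the right of 0 and lower genes to the left. Ethanol against water has 0 calls, the single treatments have 1251 to 2378, and the interactions have 1 and 2.

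In seedlings that also received ABA, the peptide raised 620 genes and lowered 299. Lsat_1_v5_gn_1_60060 stood at 0.0932 ± 0.125 CPM in ABA and at 2.13 ± 0.386 CPM in CLE12p with ABA (SD, n = 3), a log2 fold change of 4.44 ± 0.67 (SE; adjusted p = 3.09e-04). Single ABA libraries held 0 to 5 counts of it, so the size of this change is uncertain. The same gene fell with ABA (-3.26; adjusted p = 0.00938) and rose with CLE12p alone (2.62; adjusted p = 5.54e-04) and with ACC (1.75; adjusted p = 0.0156). Lsat_1_v5_gn_6_96701, which had the highest fold change among the genes named for CLE12p alone, rose by 3.79 ± 0.87 (adjusted p = 0.0150). However, its level in CLE12p with ABA was 18.6 ± 18.0 CPM. Its call was lost without CLE12p with ABA replicate 2 (adjusted p = 0.145) or without any 1 of the 3 ABA libraries. Lsat_1_v5_gn_0_6400 fell from 57.8 ± 16.4 to 8.76 ± 3.62 CPM (-2.72 ± 0.57; adjusted p = 0.00705; 0.0526 without CLE12p with ABA replicate 2), and Lsat_1_v5_gn_8_10000 fell to 0.856 ± 0.276 CPM (-2.14 ± 0.32; adjusted p = 2.91e-04). The number of calls fell to 381 without CLE12p with ABA replicate 2 and to 436, 505 and 523 without ABA replicates 1, 2 and 3.

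In seedlings that also received ACC, the peptide raised 763 genes and lowered 404. Lsat_1_v5_gn_8_78801 rose from 3.56 ± 1.18 to 46.1 ± 18.8 CPM (SD, n = 3), by 3.69 ± 0.27 on the log2 scale (SE; adjusted p = 8.96e-09). It also rose with the peptide alone (2.72; adjusted p = 6.69e-07) and beside ABA (2.12; adjusted p = 2.00e-04), and did not pass the test with ACC alone (-0.54; adjusted p = 0.323). Lsat_1_v5_gn_8_6481 rose by 3.49 ± 0.46 (adjusted p = 3.64e-05). Lsat_1_v5_gn_1_95341 fell from 458 ± 130 to 91.2 ± 29.9 CPM (-2.33 ± 0.60; adjusted p = 0.0238), and Lsat_1_v5_gn_1_57701 fell by 1.81 ± 0.43 on the log2 scale (adjusted p = 0.0132). Both calls were lost, with both genes still lower, without ACC replicate 2 (-2.08 and -1.60), CLE12p with ACC replicate 2 (-2.22 and -1.57) or replicate 3 (-2.18 and -1.78), and the first also without ACC replicate 3 (-2.38; adjusted p = 0.0502). The number of calls was 610 without ACC replicate 2 and 712 without CLE12p with ACC replicate 2.

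The peptide's effect recurred across the 3 backgrounds, which share no library. Across 18908 genes, the fold changes of CLE12p alone correlated with those in ABA (Pearson r = 0.60, Spearman rho = 0.41) and with those in ACC (0.55 and 0.40), and those in ABA with those in ACC less closely (0.34 and 0.17). Of the genes called both alone and in ABA, all 446 changed in the same direction. Of those called both alone and in ACC, 523 changed in the same direction and 1 in the opposite. Of those called both in ABA and in ACC, 312 changed in the same direction and 13 in the opposite. Among the latter, 12 rose in ABA and fell in ACC, where independent lists would share 10.7. Lsat_1_v5_gn_1_95341 was such a gene, with log2 fold changes of 2.11 in ABA (adjusted p = 0.0487) and -2.33 in ACC. In all 3 backgrounds 261 genes rose and 15 fell, where independent lists of these lengths would share 0.879 and 0.0511. The 261 genes rose by a median of 1.91-fold alone, 1.73-fold in ABA and 1.74-fold in ACC.

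**Figure D3:**
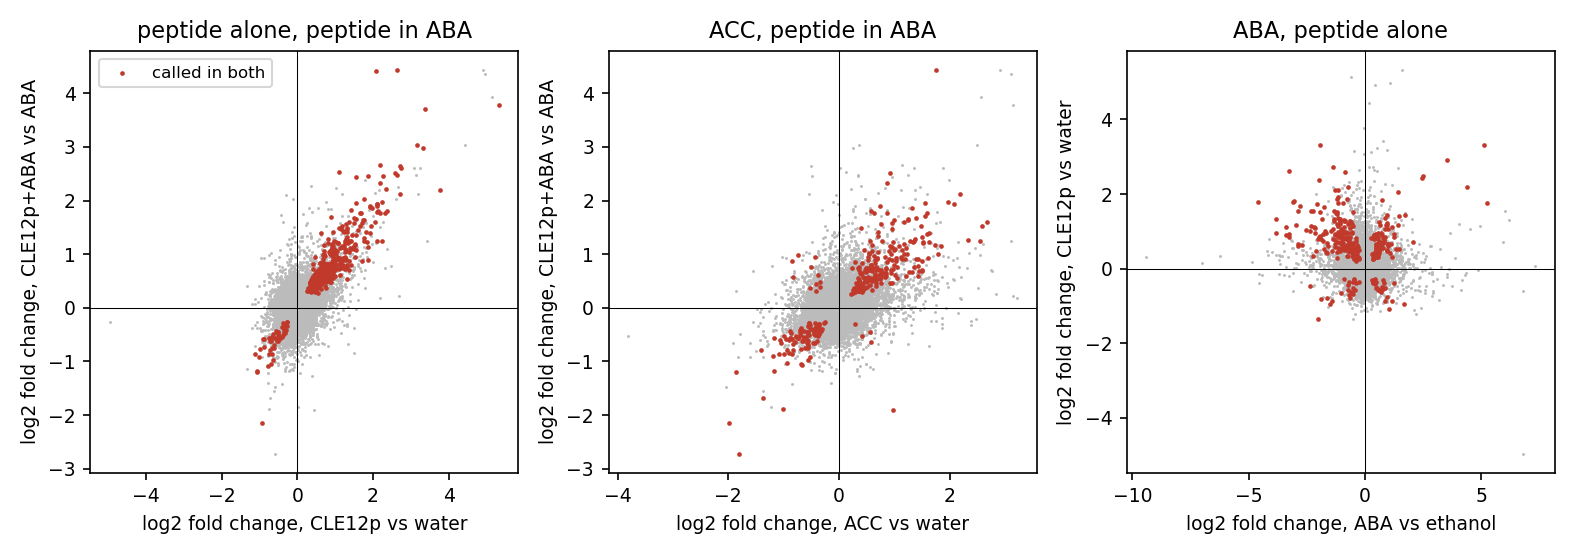
Log2 fold changes of single genes in pairs of comparisons that share no library, in grey for genes with a mean of at least 1 log2 CPM and in red for genes called in both comparisons. The peptide alone and the peptide in ABA rise together (r = 0.60), ACC and the peptide in ABA share most directions (r = 0.43), and ABA and the peptide alone do not (r = -0.08).

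Interactions tested whether the peptide's effect differed with and without a hormone. With ABA, 1 gene passed. Lsat_1_v5_gn_1_77780 fell with the peptide in water but stood at 6.60 ± 0.112 CPM in ABA and 8.74 ± 1.06 CPM in CLE12p with ABA (SD, n = 3), an interaction of 1.74 ± 0.25 on the log2 scale (SE; adjusted p = 0.0183). Its level was 17.1 ± 1.72 CPM in water and 9.54 ± 3.78 CPM in ethanol. With ethanol in place of water on the side without ABA, its interaction was 0.91 ± 0.27 (SE; adjusted p = 0.501) and edgeR called 0 genes, with 1414 at an unadjusted p below 0.05. The labels do not say whether ABA and CLE12p with ABA held ethanol, and 1.74 is measured against water. With ACC, 2 genes passed, both of which rose with ACC alone and with CLE12p alone and did not pass the test for the peptide in ACC. Lsat_1_v5_gn_5_104920 had an interaction of -1.07 ± 0.17 and Lsat_1_v5_gn_6_12161 of -2.79 ± 0.43 (adjusted p = 0.0246 for both). Levels of the latter were 2.34 ± 0.763 CPM in water, 13.7 ± 5.62 in ACC, 11.1 ± 3.06 in CLE12p and 9.27 ± 2.63 in both. The call with ABA was lost without water replicate 2 or 3, any ABA library, CLE12p replicate 1 or 3, or CLE12p with ABA replicate 1 or 2 (adjusted p from 0.0673 to 0.102). Both calls with ACC were lost without water replicate 1 or 2, ACC replicate 1 or CLE12p with ACC replicate 3 (adjusted p from 0.0871 to 0.169), and when only the libraries compared were fitted (adjusted p of 0.118 and 0.0669). The counts changed with the test, to 16 and 39 genes in DESeq2, and without single libraries, to between 0 and 4 for ABA and between 0 and 29 for ACC, the highest without CLE12p replicate 2. At an unadjusted p below 0.05 there were 1837 and 1886 genes.

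As a set, the ABA response showed no stable change in size with the peptide. Over 3118 ABA response genes (1597 rising, 1521 falling), the signed difference between CLE12p with ABA and ABA had a median of 0.03 on the log2 scale, with an interquartile range of -0.16 to 0.23 (fry adjusted p = 0.00417 over the 2 response tests). These genes and their signs were chosen partly by CLE12p with ABA, which can push the median above 0. Its sign and p-value therefore do not show a larger ABA response, and a smaller response could be masked. Over the same genes, CLE12p with ABA against CLE12p had a median of 0.54 in the direction of ABA, and ABA against ethanol had 0.63. The controls of these values differ, and ethanol took part in the choice of genes, so the values do not settle the size either. In water, where no ABA was given, the change of the same genes, signed by the direction of ABA, had a median of 0.04 (interquartile range -0.14 to 0.25, 57.3% of them above 0) and passed the fry test without adjustment. The median was 0.10 in the rising and -0.01 in the falling genes, so within this set the median shift toward ABA lay in the rising genes. The set was chosen partly by the peptide's effect in ABA, which correlated with that in water (r = 0.60). Of the 2378 genes called for ABA against ethanol, a choice without peptide libraries, 45.2% had the same sign with the peptide in water. The shift toward ABA therefore did not hold with that choice. Per library, the ABA response score was 0.906 ± 0.00524 in ABA and 0.943 ± 0.00642 in CLE12p with ABA (SD, n = 3; exact permutation p = 0.1, the smallest possible). The direction was not stable. Among the 200 genes with the smallest p the median was -0.10, among genes with an absolute log2 fold change of at least 1 it was -0.04, and with genes chosen against water it was 0.0015, none of them past the threshold. Without ethanol replicate 1 it was -0.0193, also not past the threshold. The median was 0.0423 without ethanol replicate 2, 0.0153 without ABA replicate 2, 0.0170 without ABA replicate 3, and 0.0658 and 0.0498 without CLE12p with ABA replicates 1 and 3. In simulated counts in which the peptide left 75% of each ABA change, the same step gave a median of -0.22, past the threshold, and with 100% left it gave 0.0042, not past it. Each setting was drawn once, and the simulated peptide had no effect of its own. The simulation therefore cannot show how far the choice of genes pushed the measured median.

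ACC response genes were moved further in the direction of ACC when the peptide was present. Over 3011 ACC response genes (1619 rising, 1392 falling), the signed difference between CLE12p with ACC and ACC had a median of 0.11 with an interquartile range of -0.05 to 0.29 (fry adjusted p = 0.0154). The peptide moved the same genes in the direction of ACC in water (median 0.18) and beside ABA (0.15), where no ACC was given. The signed interaction was -0.07 (fry adjusted p = 0.444 over 4 tests), so a change in the ACC effect itself did not pass the test. The ACC response score was 0.580 ± 0.0452 in ACC and 0.729 ± 0.0476 in CLE12p with ACC (SD, n = 3; exact permutation p = 0.1, the smallest possible). The difference was no longer past the threshold without ACC replicate 2 (median 0.0877) or among genes with an absolute log2 fold change of at least 1 (median 0.17).

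**Figure D4:**
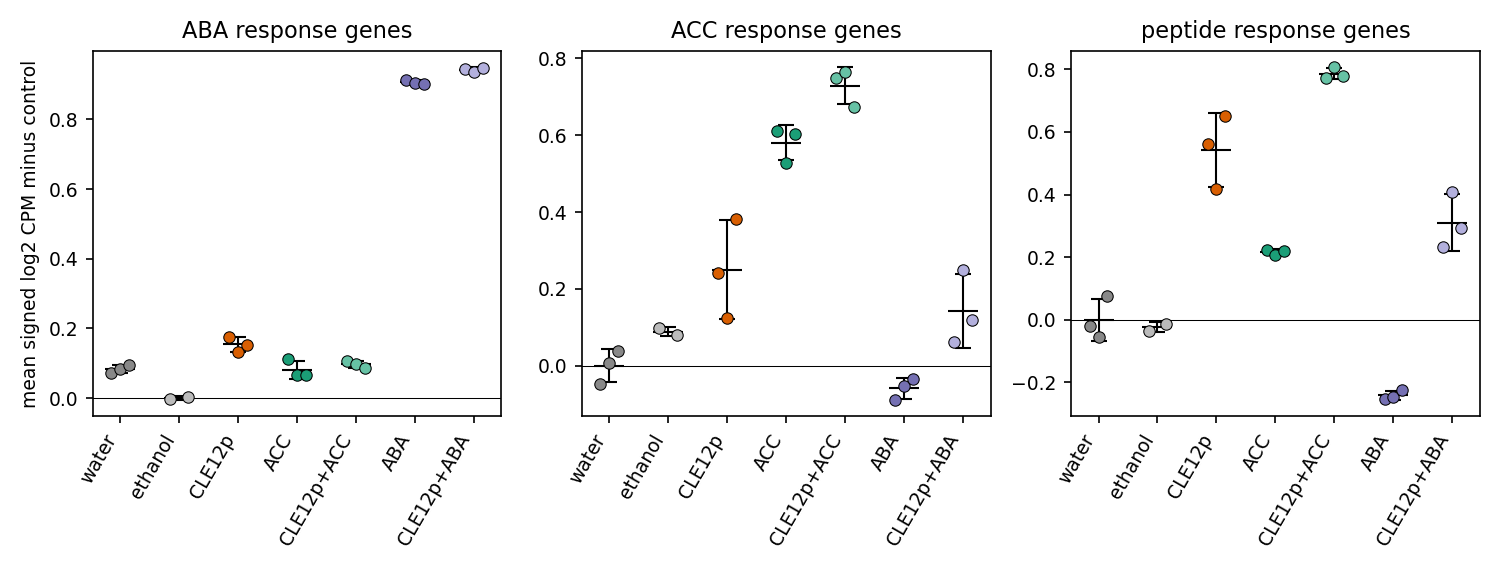
Mean signed log2 CPM per library over the ABA response genes (minus the ethanol mean), the ACC response genes (minus the water mean) and the peptide response genes (minus the water mean), with 1 point per library and bars for the group mean and SD. Peptide response genes were chosen from CLE12p with ABA against ABA and CLE12p with ACC against ACC, so that only water, ethanol and CLE12p played no part in their choice. The 3 CLE12p libraries lie between 0.417 and 0.650 on the peptide score.

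Overlaps tell which genes the treatments moved together. ACC and CLE12p called 480 genes in the same direction (375 higher in both, 105 lower in both) and 15 in opposite directions, where independent lists would share 50.7 higher and 7.23 lower genes. Both comparisons use the same water libraries. Their fold changes correlated with r = 0.59 and a covariance of 0.0652, whereas unchanged groups simulated against shared controls gave a median r of 0.50, a covariance of 0.0142 and at most 0 shared calls. Splitting 3 water libraries would leave fewer than 2 in a part, so part of the excess may come from the shared controls. Pairs with no common library gave r = 0.48 for ACC against ethanol with CLE12p against water (386 genes in the same direction, 16 opposite) and r = 0.43 for ACC against water with CLE12p with ABA against ABA (304 and 16). The overlap in the same direction was 825 genes without CLE12p replicate 2, 318 and 287 without CLE12p replicates 1 and 3, and 224 and 242 without water replicates 1 and 2.

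ABA and CLE12p, compared without any common library, had nearly unrelated fold changes (r = -0.08, between -0.11 and -0.07 without single libraries). Of 325 genes called in both, 187 fell with ABA and rose with CLE12p, against 51.01 for independent lists, and 24 rose with ABA and fell with CLE12p, against 12.0. A further 91 rose in both, against 52.5, and 23 fell in both, against 11.6. The number of genes with opposite directions was 211, and 133 without water replicate 2. The number with the same direction was 114, and it was 70 without ethanol replicate 1, 60 without ethanol replicate 2, 70 without water replicate 1 or 2, 74 without CLE12p replicate 1 and 197 without CLE12p replicate 2. ABA and ACC also gave opposite directions more often than the same direction among genes called in both (314 and 208), with r = -0.13.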

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

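The test of the CLE12p-with-ABA libraries for control RNA was chosen only after the result was seen, and so were the set of 4 interaction tests over response genes, the interaction against ethanol, the sorting of splits by what they exchange and the test of rises without scaling factors; the other tests below were fixed before their results were seen.

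Differences between backgrounds that passed a test of the difference itself came from the interactions. Lsat_1_v5_gn_1_77780 responded to the peptide differently with ABA and in water, by 1.74 on the log2 scale, and by 0.91 when ethanol took the place of water, which did not pass the test (adjusted p = 0.501). The labels do not say whether ABA and CLE12p with ABA held ethanol. Lsat_1_v5_gn_5_104920 and Lsat_1_v5_gn_6_12161 responded differently with ACC and without it, by -1.07 and -2.79. Over the ABA response genes, the peptide's signed effect was lower with ACC than without it, by a median of -0.0524 (fry adjusted p = 0.0235 over 4 such tests), with -0.105 in the rising and -0.000880 in the falling genes. These genes were signed partly by the peptide's effect in ABA. That effect correlated more closely with the peptide's effect in water (r = 0.60) than with that in ACC (r = 0.34). The choice itself favours a lower value with ACC, so this difference does not show that ACC altered the peptide's effect. The same genes gave -0.0229 for the interaction with ABA (fry adjusted p = 0.444). No group held 4 or more libraries, so single libraries were not tested for distance from their group.

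Splits of the libraries did not decide whether the interaction counts lie above chance. When only the libraries of an interaction were fitted, 1 gene passed for ABA, 5 of 100 splits gave at least as many with the real one included, and 138 was the highest of the others. For ACC 1 gene passed, 13 of 100 splits gave at least as many, and the highest of the others was 40. Every other split with a call (4 for ABA, 12 for ACC) exchanged unequal numbers of peptide libraries alone and with the hormone, and by its design such a split holds part of the peptide's main effect. The 36 splits that exchanged equal numbers gave 0 calls for either interaction, but they place libraries with and without the peptide in 1 group, which widens the spread the test uses. For the 3 against 3 comparisons there are 10 splits, of which 1 is the real one, too few for a share under 0.05. The real splits, fitted on the libraries compared alone, gave 2689 calls for ACC, 743 for CLE12p, 1112 for CLE12p with ABA and 1302 for CLE12p with ACC, and the highest of the other splits gave 0 in each of them.

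Peptide libraries spread along the peptide's own response: with genes chosen from the other backgrounds, the CLE12p score ran from 0.417 (replicate 2) to 0.650 (replicate 3), a range of 0.233, where water ranged over 0.130 and CLE12p with ACC over 0.0329. Depth does not account for the spread in CLE12p, since after thinning every library to the smallest library total the range was 0.231, above the 0.129 of the widest group without peptide. An offset in scaling would move rising and falling genes to opposite sides, whereas replicate 2 lay below its fellows in both, by -0.23 in the rising and -0.101 in the falling genes. In CLE12p with ABA, replicate 1 had the lowest peptide score and replicate 2 the highest, and on genes called for ABA against ethanol the ABA score of the first lay 0.0777 above the second, where mixing a control library into the second down to the same peptide score lowered it by 0.409 to 0.586, which argues against RNA from untreated seedlings in replicate 1. RNA from seedlings given ABA alone, an uneven dose or uptake of the peptide and differences between batches of seedlings stay open and were not tested.

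A preponderance of rises marked the peptide alone. The share of rises was 74.0% or more under 3 other scalings and 74.4% or more without any 1 of the libraries compared, against 81.5% with all of them. The lowest share among the scalings came from DESeq2, which also changes the test. In edgeR the share was 78.5% with RLE factors and 75.7% without scaling factors. No single library therefore accounts for it, and neither does the choice among these scalings. The scalings could change little, since the TMM factors ran only from 0.961 to 1.03, and RLE and DESeq2 factors rest on the same method. Each sets library totals or typical genes equal, so a shift of most genes cannot be excluded. No biological explanation was tested, since the genes could not be matched to functions.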

How the results depend on the processing

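Overlap alternatives, CLE12p against water without scaling factors, the ABA interaction against ethanol, and leaving out ethanol, water or CLE12p libraries for the hormone responses were chosen after seeing the data; the others were fixed before the data were examined. Directions held in every alternative of the named genes (342 values, of which 303 kept their side of the threshold, 39 lost it and 0 reversed). Most of these genes were chosen for no overlap between the libraries compared. Leaving out 1 library could then hardly reverse them, so the 0 reversals say little about stability. RLE factors left the counts of the 8 comparisons and the overlaps within 1.5 times, and a mean of at least 50 counts, not run on the overlaps, those of the 8 comparisons. A minimum absolute log2 fold change of 1 cut the calls by its construction to 890 for ABA, 380 for ACC, 306 for CLE12p, 207 for CLE12p with ABA and 239 for CLE12p with ACC. Pooling the controls raised those for ABA to 3916 and for CLE12p to 1943, with more control libraries. With only the libraries compared, CLE12p had 743 calls and the ACC interaction 1. ABA had 3284, ACC 2689, CLE12p with ABA 1112 and CLE12p with ACC 1302. The fit with the spread pooled over all groups thus called more genes for CLE12p alone and fewer for these 4 comparisons. For the interactions with ABA and ACC, DESeq2 gave 16 and 39, and no filter 2 and 10, and ethanol as control gave 0 with ABA; the cause was not tested. The ABA response with CLE12p reversed to -0.104 among the 200 genes with the smallest p and to -0.0412 among genes with an absolute log2 fold change of at least 1, and fell to 0.00153 with genes chosen against water; the ACC response was 0.173, no longer past the threshold, among genes with an absolute log2 fold change of at least 1. The causes were not tested. Leaving out each library in turn gave 0 to 1 calls for ethanol, 1396 to 1923 for ABA, 1097 to 1658 for ACC, 636 to 2073 for CLE12p, 381 to 1018 for CLE12p with ABA, 610 to 1093 for CLE12p with ACC, 0 to 4 for the ABA interaction and 0 to 29 for the ACC interaction, a median of -0.0193 (without ethanol replicate 1, no longer past the threshold) to 0.0658 for the ABA response and of 0.0877 to 0.147 for the ACC response, 224 to 825 genes for the overlap of ACC with CLE12p and 133 to 313 for that of ABA with CLE12p in opposite directions, with 60 to 197 in the same direction. Each such fit has 1 library fewer, but the counts differed widely with which was left out, and the cause was not tested; without 1 ethanol library the other is assumed to vary like the other groups. Replicate numbers did not pair the libraries (mean correlation of deviations -0.03 over 57 same-numbered pairs, 2 of them above 0.1; 1 library correlated best with its own number). A replicate block changed the ACC interaction from 2 calls to 0 and moved no other count by over 1.5 times. Gene lists and their alternatives were not run, since no list had members. Genes with few counts carry wide intervals at this depth.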

Other observations

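The tests of shared controls, of a response to any compound and of peptide genes under ABA were chosen only after the overlap was seen.

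Comparing the single treatments showed where the peptide's 1251 calls lay. Of its 1019 rising genes, 482 were called neither with ABA nor with ACC, 248 rose with ACC and were not called with ABA, and 90 rose with ACC and fell with ABA. Of its 232 falling genes, 104 were called in neither and 81 fell with ACC and were not called with ABA. There were 37 genes that rose with ABA, ACC and CLE12p, where independent lists would share 2.61, and 12 that fell with each of them, where such lists would share 0.362. However, ACC and CLE12p alone shared 375 rising and 105 falling genes, so much of this excess restates that overlap. Lists of ABA and CLE12p also shared more genes than independent lists in opposite directions, with 187 that fell with ABA and rose with CLE12p. The excess therefore does not show a response common to all 3 treatments. ACC and CLE12p were compared with the same water libraries, and what this adds to the 37 and 12 was not tested. The combined treatments changed more genes against their controls than the single ones, with 3375 calls for CLE12p with ABA against ethanol and 4244 for CLE12p with ACC against water.

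Peptide genes went both ways with ABA. Among 2506 peptide genes chosen without any library that held ABA, ABA called 367 against the peptide's direction and 202 with it, and of the 1669 that rose with the peptide 266 fell with ABA and 139 rose. Over the whole set the signed ABA change had a median of -0.05 with an interquartile range of -0.29 to 0.15 and did not pass the fry test. Over the 3118 ABA response genes, the peptide's change in water signed by the direction of ABA had a median of 0.04 and passed the fry test without adjustment, with 0.10 in the genes that rise with ABA and -0.01 in those that fall. Those genes were signed partly by CLE12p with ABA, which can push this median above 0. Of the 2378 genes called for ABA against ethanol, 45.2% had the same sign with the peptide in water.

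Genes shared by the peptide and ACC formed the clearest overlap. Shared water controls cannot be the whole of it, since r was 0.427 between comparisons with no common library, and between 0.296 and 0.461 without single libraries. A response to any added compound was looked for in the 480 shared genes with ABA against ethanol. Their signed ABA change had a median of -0.0862 (interquartile range -0.48 to 0.20), against 0.698 with ACC, by whose call they were chosen. Ethanol is itself an added compound, so a response that it also gave would cancel here. Effects of ABA itself could also hide such a response. The values therefore do not decide whether any added compound moves these genes. A hypothesis is that the peptide and ACC act through a common route, in which case the combination may give less than the sum on shared genes. Over 812 genes changed the same way in both effects, the signed interaction was -0.0797 with an interquartile range of -0.29 to 0.12 and did not pass the fry test, so the values do not tell a common route from independent effects.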
